A study of Escherichia coli with 24 samples.

How the data were processed

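The deposited values are intensity values written by the authors, on a linear scale, for 7290 probe sets of an Affymetrix E. coli antisense genome array. Per the labels' protocols, cells grew in LB with ampicillin at 30 °C to OD660 0.3, the antibiotic was removed, and the culture was shifted to 42 °C and diluted 100-fold at OD660 0.5. RNA was taken with RNA Protect and Trizol, and 10 µg of it was made into biotinylated cRNA, per the same protocols. Per the submitters' processing notes the signals came from GCOS 1.0. The deposited array medians of 1.001 to 1.009 show a division by the array median. Background settings and RNA quality values are not given in the sources used here.

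The array holds 4345 gene probe sets, 2886 intergenic probe sets and 59 phage or plasmid probe sets, and only the gene probe sets entered the main tests. Of the gene probe sets, 4183 match a locus tag of the reference annotation (assembly ASM584v2), which served for names only; 162 do not. The platform table gave 1 symbol for 3804 probe sets and several for 594. No genome build is given for the positions in the probe set names. Among the tested genes 115 are read by probe sets with a shared-target suffix, and their gene is uncertain.

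The 2% trimmed means of the arrays ran from 3.32 to 5.13, more than 10% apart, so the fixed rule called for quantile normalization; the deposited scaling is an alternative. A pseudocount of 0.106 (the 10th percentile) was added, log2 was taken, and the 20% of gene probe sets with the lowest mean were left out, which kept 3476 genes. Groups were compared by limma 3.58.1 under R 4.3.3 with a mean per strain and time, moderated variance with an intensity trend (10 residual and 7.17 prior degrees of freedom) and Benjamini-Hochberg adjustment within each comparison. A gene was called at adjusted p under 0.05. No fold threshold was applied.

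The groups were 3 strains at 4 times with 2 biological replicates each, 24 arrays in all. The pTN11 columns for replicate 2 at 1 h and replicate 2 at 1 h 50 min hold identical values in all 7290 probe sets. The fixed design fits all 24 columns. The fit behind the values printed departs from it: both identical columns were left out, because one library cannot stand for 2 times and the label at fault is not given in the sources used here. This decision was taken after the identity was seen and before any call was compared. It leaves 22 arrays and 1 array for pTN11 at 1 h and at 1 h 50 min, whose spread is taken from the other groups. The fit as first written, with all 24 columns, is given beside each main count.

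The comparisons fixed were pTN9 against pTN11, pTN9 against pHSG415 and pTN11 against pHSG415 at each time, each time against 0 h within a strain, and the difference between pTN9 and pTN11 in their change from 0 h. Of the genes called, the highest and lowest log2 fold changes were named (10 each for pTN9 against pTN11, 5 each elsewhere) where every array of one group lay on one side of every array of the other. Up to 4 called members of each list were named as well, and recA, lexA, sulA, umuD, dinI, recN, recB, dnaK, groL, ibpA, clpB, rpoE, degP, cpxP, spy, ompF, ompC and the plasmid marker bla were followed always. The array carries no probe set under the symbol cpxP. Lack of space keeps some of the genes so picked to the tables.

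The lists, the comparisons, the naming rule and the processing rules were set before the data were examined. The lists, written from general knowledge, are SOS, DNA repair, heat shock, sigma E, Cpx, Rcs, phage shock, porins, peptidoglycan, flagella, fimbriae, ribosomal, general stress, oxidative, iron, anaerobic, TCA, purine, reductases (ribonucleotide reductases and their partners) and toxin-antitoxin, with the prophages e14, Rac, DLP12 and Qin as 4 more. They were tested by limma camera with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Benjamini-Hochberg adjustment ran over the tests of a family. Between strains a family held 96 tests (24 lists at 4 times). For changes from 0 h in each strain, and for the difference in change, a family held the 24 lists at each time after 0 h. Members adjusted over the list alone are given in brackets after each count.

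Background was set after the data were seen, at the 95th percentile of 58 phage and plasmid probe sets on each array (0.484 to 0.936), and is used only to bound folds: where the lower group lies under it, the fold is given as at least the ratio to background. For the difference in change, each group mean below background was set to background and the difference taken again, also chosen after the data were seen. Between 2841 and 3626 genes lay above it per array. Replicates of a group correlated at 0.981 to 0.993.

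Alternatives fixed beforehand were the deposited scaling, pseudocounts at the 25th percentile (0.324) and of 1, a filter of 40% or none, no intensity trend, a replicate block, a fit to the arrays of one time, the estimated inter-gene correlation and leaving out each array. Added after the data were seen were the identical column kept at 1 h only, and kept at 1 h 50 min only. The fit to all 24 columns, fixed beforehand as the main one, became an alternative at that point.

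A self-test added changes to 200 of 3476 simulated genes with the variances and arrays of the fit. For pTN9 against pTN11 at 3 h it recovered 14%, 94%, 100% and 100% of changes of log2 0.5, 1, 2 and 3, with 6.1% false calls. At 1 h, with 1 pTN11 array, it recovered 6%, 62%, 100% and 100%, with 2.19% false calls. A raised SOS list was called, and so was 1 of the 23 other lists. The SOS and toxin-antitoxin lists share members, yafN and yafO among them, so a call of another list need not be false. Each gene was drawn independently. The self-test thus holds no deviation common to many genes of an array, and its share of false calls need not hold for the data.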

Results

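The series measured messenger RNA in E. coli MG1655 carrying one of 3 temperature-sensitive plasmids: pTN9, with the PaeR7I restriction and modification genes (r+m+), pTN11, with modification only (r−m+), and the vector pHSG415. A shift from 30 °C to 42 °C stops replication of the plasmid. Cells were taken before the shift (0 h) and after it, at 1 h, 1 h 50 min or 3 h, in 2 independent experiments, on 24 arrays in 12 groups. Of these, 22 arrays were compared, because the pTN11 columns of replicate 2 at 1 h and at 1 h 50 min are identical; pTN11 has n = 1 at those times and every other group n = 2. The number of arrays limits precision. Per the series text, growth at 30 °C was alike by OD660 and cells died only in the pTN9 strain, 4 h or more after the shift.

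Did the shift remove the plasmid's transcript alike in the 3 strains? The bla probe set, for the beta-lactamase carried by each plasmid, had a mean deposited signal of 18.5 (SD 0.311, n = 2) at 0 h in pTN9, 3.43 (SD 0.256) at 1 h, 0.878 (SD 0.115) at 1 h 50 min and 0.108 (SD 0.0213) at 3 h. In pTN11 the means were 15.96 (SD 0.0212) at 0 h, 3.35 (n = 1), 0.878 (n = 1) and 0.130 (SD 0.0184). In pHSG415 they were 28.1 (SD 6.19), 4.43 (SD 0.557), 2.91 (SD 0.509) and 0.111 (SD 0.0181). The change from 0 h to 1 h was log2 −2.14 in pTN9, −2.15 in pTN11 and −2.39 in pHSG415. By 3 h bla lay below background in every strain. At 0 h it was lower in pTN9 than in pHSG415 (log2 −0.56, SE 0.16, adjusted p = 0.0333), and the difference of pTN11 from pHSG415 was as large but not called (−0.60, SE 0.16, adjusted p = 0.391). By 1 h 50 min it was lower in pTN9 (−1.68, SE 0.16, adjusted p = 4.96e-06) and in pTN11 (−1.66, SE 0.20, adjusted p = 0.000688) than in pHSG415. It differed between pTN9 and pTN11 at no time.

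The comparison of pTN9 with pTN11 asks which transcripts depend on the restriction gene. At 3 h (n = 2 and 2) the SOS genes, which answer DNA damage, were raised in pTN9. Transcripts of umuD (b1183) and umuC, the subunits of the error-prone polymerase V, were higher by log2 5.05 (SE 0.17, 33.1-fold, adjusted p = 4.27e-13) and 4.00 (SE 0.19, 16-fold). The division inhibitor sulA (b0958) rose by 4.89 (SE 0.19, 29.7-fold, adjusted p = 1.9e-12), with signals of 96.3 and 90.65 in pTN9 against 2.208 and 2.999 in pTN11. Transcripts of recN (b2616), which acts in repair of double-strand breaks, were higher by 3.81 (SE 0.37, 14-fold), those of dinI, a modulator of RecA, by 3.06 (SE 0.21). The recombinase gene recA (b2699) was higher by 2.34 (SE 0.17, 5.05-fold, adjusted p = 2.17e-08), with 121.2 and 172.9 against 23.35 and 22.74, and lexA (b4043), the repressor of these genes, by 1.88 (SE 0.16). Of the 32 SOS genes tested, 27 were called higher and 0 lower (27 and 0 adjusted over the list alone), with a median of 1.52 (limma camera adjusted p = 1.56e-27; adjusted p = 0.00072 with an estimated correlation).

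The largest differences at 3 h lay in e14, a defective prophage of the K-12 chromosome. Transcripts of ymfL (b1147) gave signals of 54.55 and 71.81 in pTN9 against 0.104 and 0.103 in pTN11, which lie below background (log2 7.99, SE 0.26, at least 76.7-fold, adjusted p = 2.13e-13). Near it ymfJ (b1144) was 107-fold higher (6.74, SE 0.21), ymfM (b1148) at least 58.8-fold and ymfN (b1149) at least 32.3-fold. The excisionase gene xisE (b1141) was at least 41.1-fold higher, the integrase gene intE (b1140) at least 18.4-fold (6.02, SE 0.27) and the tail fibre gene stfE (b1157) at least 10-fold. The 1 member called lower was the phage repressor gene ymfK (b1145), at −0.78 (adjusted p = 0.018), named after its values were seen. Of 18 e14 genes, 15 were higher and 1 lower (15 and 1 over the list alone), with a median of 4.88, or 4.10 with genes at their bound (camera adjusted p = 3.41e-29; adjusted p = 0.00235 with an estimated correlation). The other prophages were not called by the list test. Rac had a median of −0.05 with 0 of 10 genes called (camera adjusted p = 0.99). DLP12 had −0.04 with 1 of 11 lower (1 over the list alone, adjusted p = 0.423), and Qin −0.41 with 4 of 17 lower (5, adjusted p = 0.0523). The signal filter kept 18 of 20 e14 genes on the array, but 10 of 26 for Rac, 11 of 24 for DLP12 and 17 of 33 for Qin. It uses the mean over all arrays, so a gene high in pTN9 alone can pass. Members it dropped were not compared.

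**Figure D1:**
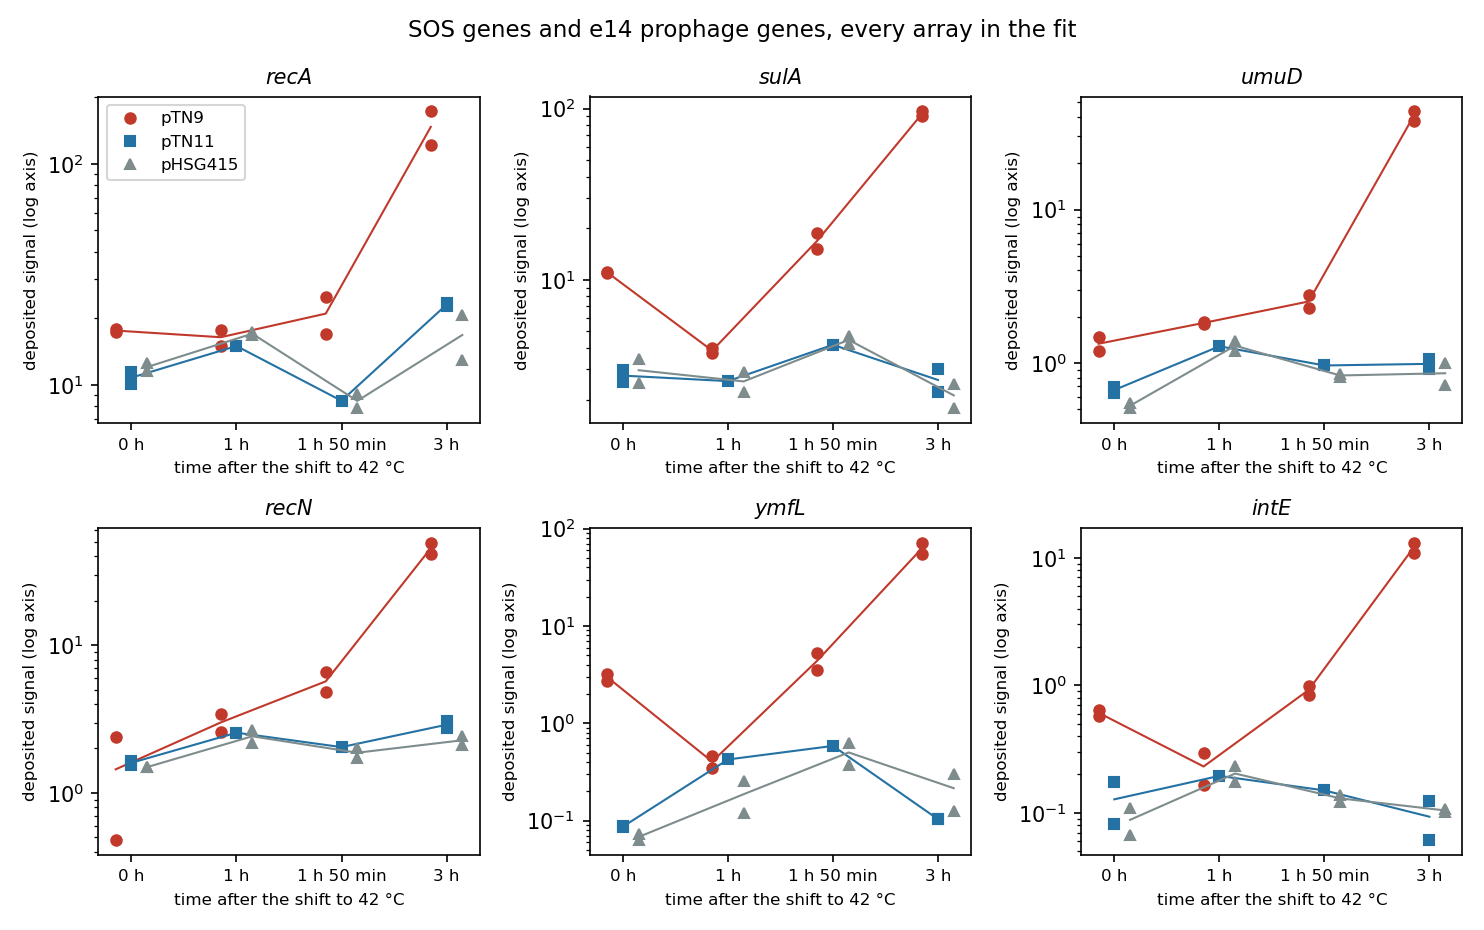
Deposited signal of recA, sulA, umuD, recN, ymfL and intE on every array in the fit, by strain and time after the shift to 42 °C. The axis is logarithmic and lines join group means.

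General stress and Rcs genes were also higher in pTN9 at 3 h. Among the former, mostly under RpoS, the periplasmic protein gene osmY (b4376) was higher by 2.91 (SE 0.16), the peroxidase gene osmC by 2.33 (SE 0.18) and otsB, for trehalose synthesis, by 2.33 (SE 0.23). The list had 11 of 19 genes higher and 0 lower (12 and 0 over the list alone), with a median of 1.38 (camera adjusted p = 3.42e-10; adjusted p = 0.0159 with an estimated correlation). In the Rcs list, a response to envelope damage, bdm was higher by at least 7.17-fold (pTN11 below background), the lysozyme inhibitor gene ivy by 1.85 (SE 0.25), osmB by 1.40 (SE 0.18) and the regulator gene rcsA by 1.31 (SE 0.21). The signal filter kept 16 of 29 Rcs genes. Of these 16, 9 were higher (11 over the list alone), with a median of 0.79, or 0.70 with genes at their bound (camera adjusted p = 4.77e-08, and adjusted p = 0.0314 with an estimated correlation). The oxidative list had 8 higher and 1 lower of 20 (9 and 1), median 0.42 (adjusted p = 0.000808; adjusted p = 0.0291 with an estimated correlation), with sufC, for iron-sulfur assembly, at 1.13 (SE 0.18).

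Motility genes were lower in pTN9 at 3 h: fliA, for the flagellar sigma factor, by −2.12 (SE 0.17, 4.35-fold), the regulator gene fliZ by −2.03 (SE 0.19), and flgI, for the P ring, by −2.69 (SE 0.26, at least 2.66-fold). Of 46 flagellar genes, 31 were lower and 1 higher (32 and 2), with a median of −1.10 (camera adjusted p = 3.01e-15), but adjusted p = 0.102 with an estimated correlation. The same loss held for TCA, median −0.39 with 9 of 30 lower and 0 higher (14 and 1; adjusted p = 0.00544, adjusted p = 0.184 with an estimated correlation, and 0.0531 without pTN9 replicate 1). It held for porins, median −0.23 with 4 of 15 lower (7; adjusted p = 0.0191, adjusted p = 0.407 with an estimated correlation, and 0.287 without pTN9 replicate 2), where ompF, for a general porin, was lower by −1.10 (SE 0.14). The class I ribonucleotide reductase gene nrdB was higher by 1.68 (SE 0.22), the periplasmic chaperone gene spy by 1.70 (SE 0.21), and recB, of the RecBCD nuclease, was lower by −0.58 (SE 0.17, adjusted p = 0.0232).

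Heat shock genes stood alike at 3 h, with dnaK at 0.18 (adjusted p = 0.536), groL at −0.26 and clpB at −0.08, none called, and only the small chaperone gene ibpA higher (0.84, SE 0.28, adjusted p = 0.045). The heat shock list had a median of −0.07, 1 of 24 higher and 1 lower (0 and 1; adjusted p = 0.818). The sigma E gene rpoE (0.56), the protease gene degP (0.57, adjusted p = 0.0699) and ompC (−0.26) were not called. The lists left did not pass the camera test. DNA repair had a median of −0.15, with 1 gene higher and 2 lower of 20 (1 and 2; adjusted p = 0.573), and Cpx −0.02, with 2 and 5 of 15 (3 and 5; adjusted p = 0.811). Sigma E stood at 0.29, with 2 and 4 of 25 (5 and 4; adjusted p = 0.208), and phage shock at 0.00, with 0 and 0 of 7 (0 and 0; adjusted p = 0.672). Peptidoglycan stood at 0.04, with 2 and 4 of 41 (2 and 4; adjusted p = 0.818), and fimbriae at −0.59, with 2 and 5 of 12 (2 and 8; adjusted p = 0.208). The ribosomal list was at −0.11, with 0 and 2 of 54 (0 and 0; adjusted p = 0.197), but at 0.18 and called higher under the deposited scaling (adjusted p = 0.0096). Iron had 0.21, with 7 and 2 of 24 (9 and 3; adjusted p = 0.094), and anaerobic −0.17, with 0 and 1 of 24 (0 and 0; adjusted p = 0.664). Purine had −0.18, with 0 and 3 of 23 (0 and 2; adjusted p = 0.229), reductases −0.32, with 2 and 0 of 8 (2 and 1; adjusted p = 0.818), and toxin-antitoxin 0.11, with 4 and 0 of 18 (4 and 0; adjusted p = 0.229).

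In all, limma called 661 genes between pTN9 and pTN11 at 3 h, 283 higher and 378 lower, of which 125 and 99 were 2-fold or more apart. With all 24 columns the count was 218, each among the 661 and in the same direction. Without pTN9 replicate 2 at 3 h it was 320, and without pTN11 replicate 2 at 3 h it was 328. The higher share was 42.8%, and 27.9% under the deposited scaling. Of 86 genes picked by the naming rule, 51 kept their call with all 24 columns; fliZ, ibpA and recB were among those that lost it.

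The comparison at 1 h 50 min asks which genes differed by then, and part of the differences stood already at 0 h, as given below. The SOS genes sulA (log2 2.16, SE 0.23), dinI (1.88, SE 0.26), recA (1.37, SE 0.21) and umuD (1.36, SE 0.21) were higher in pTN9 (n = 2) than in pTN11 (n = 1). So were the e14 genes ymfJ (3.16, SE 0.26, at least 8.77-fold) and ymfN (3.31, SE 0.38, at least 3.22-fold). Of 32 SOS genes, 6 were higher and 0 lower (11 and 0), median 0.35 (adjusted p = 1.13e-12; adjusted p = 0.00769 with an estimated correlation). Of 18 e14 genes, 8 were higher (10), median 1.30, or 0.42 with genes at their bound (adjusted p = 6.56e-18; adjusted p = 0.00941 with an estimated correlation). The difference in change from 0 h was called for neither list, with medians of 0.21 for SOS and 0.02 for e14. SOS gained the call with either other pseudocount, no intensity trend, the replicate block and some omissions of an array. At 1 h the SOS list stood at 0.09 and was not called, and the step from 1 h to 1 h 50 min was not tested. An onset after the shift is thus not shown by these values, nor is it excluded. The glycerol 3-phosphate genes glpA (2.39, SE 0.54, at least 4.32-fold) and glpT (2.17, SE 0.42) were higher. Lower were the small heat shock genes ibpB (−3.51, SE 0.53) and ibpA (−2.77, SE 0.34), the acetate permease gene actP (−2.71, SE 0.50), sucD (−1.29, SE 0.26) and gltA (−1.16, SE 0.25) of the TCA cycle.

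The heat shock list at 1 h 50 min had 0 higher and 4 lower of 24 (0 and 13), median −0.69 (adjusted p = 4.57e-18, but adjusted p = 0.0534 with an estimated correlation). TCA had 4 of 30 lower (5), median −0.35 (adjusted p = 1.67e-08; adjusted p = 0.0276 with an estimated correlation), and with all 24 columns the median was 0.73 and the list was called higher (adjusted p = 1.84e-07). The oxidative list had 0 genes called by limma (0 higher and 3 lower over the list alone), median −0.19 (adjusted p = 0.00174; adjusted p = 0.0314 with an estimated correlation; 0.56 with all 24 columns). General stress and flagella stood opposite to their sign at 3 h, and neither passed with the estimated correlation. General stress had a median of −0.27 with 0 of 19 genes called (0 higher and 2 lower over the list alone; adjusted p = 4.37e-05; adjusted p = 0.0639 with an estimated correlation), and with all 24 columns it stood at 0.71 and was called higher (adjusted p = 0.000179). Flagella had 0.26 with 0 of 46 called (0 and 0; adjusted p = 3.62e-05; adjusted p = 0.428 with an estimated correlation). Rcs, at 0.02, was not called (adjusted p = 0.956). Ribosomal (0.28), purine (0.39) and fimbriae (0.37) were called higher with the preset correlation only (adjusted p = 0.102, 0.184 and 0.119 with an estimated correlation). The count was 50 genes, 31 higher and 19 lower, of which 22 and 16 were 2-fold or more apart, and 28 with all 24 columns. Without pTN9 replicate 1 at 1 h 50 min it was 86 and without replicate 2 it was 13. Of 31 genes picked by the naming rule 10 kept their call with all 24 columns, among them ymfJ, ymfN, sulA, recA, umuD and glpT; dinI, glpA, ibpA, ibpB, actP, sucD and gltA lost it.

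At 1 h limma called 4 genes, all higher in pTN9 (n = 2) than in pTN11 (n = 1). The NADH oxidoreductase gene hcr was at 1.79 (SE 0.34, adjusted p = 0.0483, at least 1.37-fold). The ribosomal RNA genes rrlC (0.84), rrfG (0.77) and rrfH (0.59) are read by probe sets shared among copies. At unadjusted p under 0.05 there were 98. With all 24 columns the count was 0, as it was without pTN9 replicate 2 at 1 h. Not called were recA (0.17), sulA (0.61), dnaK (−0.04) and ibpA (0.11). The SOS list had a median of 0.09 (adjusted p = 0.197) and the heat shock list 0.03 (adjusted p = 0.938). The e14 list was at 0.23 with 0 genes called (1 higher over the list alone; adjusted p = 0.000846), but adjusted p = 0.199 with an estimated correlation and 0.111 without pTN9 replicate 2. Flagella (0.16), phage shock (−0.12) and anaerobic (−0.06) passed with the preset correlation only (adjusted p = 0.764, 0.16 and 0.184 with an estimated correlation), with 0 genes called.

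At 0 h, before the shift, pTN9 and pTN11 already differed (n = 2 and 2). The heat shock genes were lower in pTN9: ibpA (b3687) by −3.53 (SE 0.28, 11.5-fold), with signals of 2.825 and 4.117 against 30.03 and 43.59, ibpB (b3686) by −3.61 (SE 0.43), dnaK (b0014) by −1.93 (SE 0.18), the disaggregase gene clpB by −1.84 (SE 0.20) and the chaperonin gene groL by −1.39 (SE 0.22). The SOS genes sulA (1.78, SE 0.19), yebG (1.09, SE 0.15), dinI (1.06, SE 0.21), umuD (0.84, SE 0.17) and recA (0.50, SE 0.17, adjusted p = 0.0476) were higher, while lexA (0.19) and recN (−0.47, pTN9 arrays 0.482 and 2.409) were not called. The e14 genes ymfL (3.79, SE 0.26, at least 3.28-fold) and ymfJ (3.48, SE 0.21, at least 5.77-fold) were higher. So were the isoleucine synthesis gene ilvC (2.22, SE 0.23) and ycdZ, of unknown function (2.58, SE 0.16). Lower were tnaA, for tryptophanase (−4.45, SE 0.26), the pyruvate carrier gene btsT (−3.39, SE 0.21), dsdA, for serine breakdown (−3.35, SE 0.28), putA, for proline breakdown (−3.26, SE 0.21), spy (−2.15, SE 0.21) and the class Ib reductase gene nrdE (−1.75, SE 0.34).

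**Figure D2:**
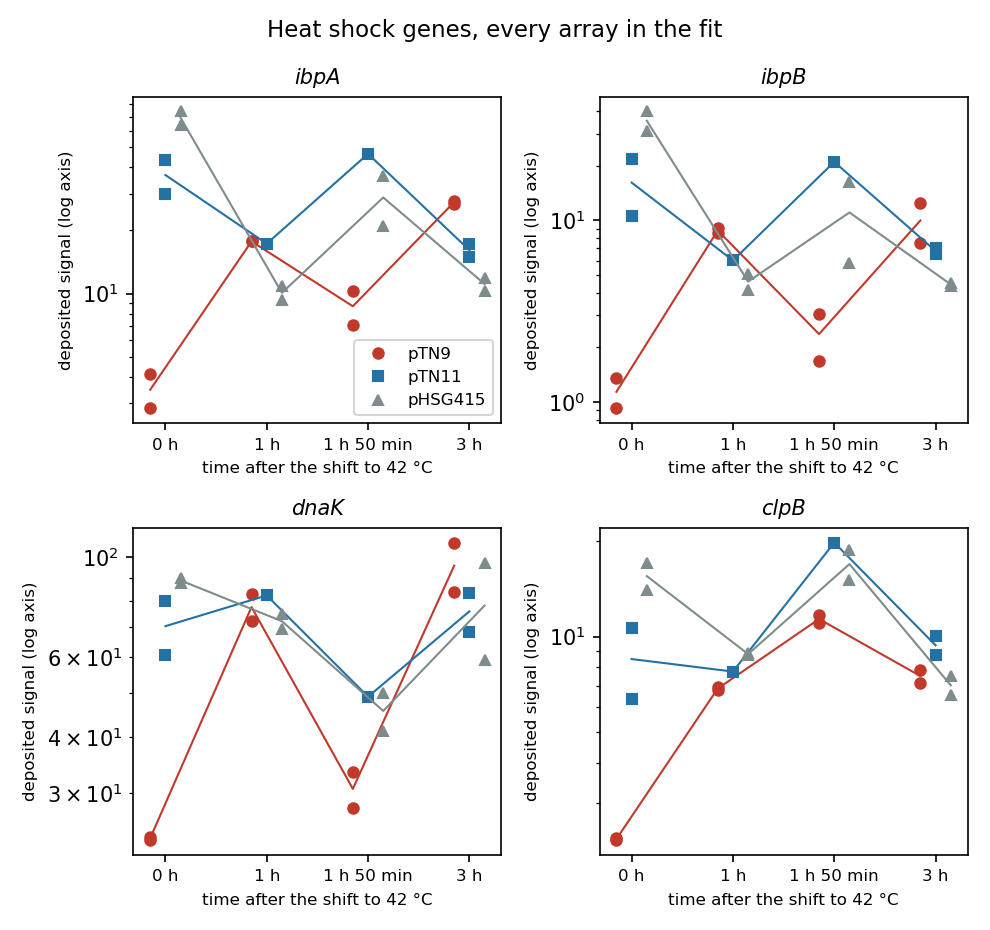
Deposited signal of ibpA, ibpB, dnaK and clpB on every array in the fit, by strain and time after the shift to 42 °C. The axis is logarithmic and lines join group means.

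By list at 0 h, reductases fell to a median of −1.07, 6 of 8 lower (6, with 1 higher; adjusted p = 7e-04; adjusted p = 0.0314 with an estimated correlation). The e14 list had 11 of 18 higher (11), median 1.55, or 0.44 with genes at their bound (adjusted p = 2.23e-09; adjusted p = 0.0376 with an estimated correlation). Heat shock had 20 of 24 lower (21, with 1 higher), median −1.02 (adjusted p = 2.06e-16), but adjusted p = 0.0625 with an estimated correlation. SOS had 8 of 32 higher (8), median 0.30 (adjusted p = 0.00133; adjusted p = 0.117 with an estimated correlation). Ribosomal had 17 of 54 higher (20), median 0.22 (adjusted p = 6.98e-07; adjusted p = 0.259 with an estimated correlation), and purine 8 of 23 higher (10), median 0.48 (adjusted p = 1.72e-05; adjusted p = 0.255 with an estimated correlation). General stress had 9 of 19 lower (9), median −0.61 (adjusted p = 0.000138; adjusted p = 0.0827 with an estimated correlation). Cpx (−0.42), iron (0.35) and TCA (−0.37) passed with the preset correlation only (adjusted p = 0.0625, 0.16 and 0.181 with an estimated correlation). The Rcs list had a median of 0.07 while camera pointed lower (adjusted p = 0.811).

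At 0 h 721 genes were called, 357 higher and 364 lower, of which 78 and 156 were 2-fold or more apart, against 162 with all 24 columns. The count was 396 without pTN9 replicate 1 at 0 h and 477 without pTN11 replicate 1 at 0 h. The higher share was 49.5%, and 63.3% under the deposited scaling. Of 78 genes picked by the naming rule 40 kept their call with all 24 columns; tnaA, dinI and recA were among those that lost it. From 0 h to 3 h, 30 genes were higher at both times, 29 lower at both, 66 higher then lower and 48 lower then higher, where 29.1, 39.6, 38.8 and 29.6 were expected of independent calls.

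The comparison of pTN9 with pHSG415 asks whether the same genes differ from the empty vector (n = 2 and 2). At 3 h umuD (5.23, SE 0.17), sulA (5.11, SE 0.19), recN (4.07, SE 0.37) and umuC (3.75, SE 0.19) were higher, with ymfL (7.36, at least 58.9-fold) and ymfJ (6.79, 111-fold). So were bdm (at least 5.50-fold), osmC (2.58, SE 0.18), osmY (2.57, SE 0.16), ivy (2.06), sufA (1.49), nrdB (1.38) and ibpA (1.22, SE 0.28). Lower were flgI (−2.73, SE 0.26, at least 2.73-fold), fliA (−2.19, SE 0.17) and ompF (−1.47, SE 0.14). SOS had 26 of 32 higher (27), median 1.53 (adjusted p = 0.000646 with an estimated correlation). The e14 list had 15 of 18 higher and 1 lower (16 and 1), median 4.81, or 3.70 with genes at their bound (adjusted p = 0.00218 with an estimated correlation). General stress had 11 of 19 higher (12), median 1.26 (adjusted p = 0.00888 with an estimated correlation), and oxidative 7 of 20 higher (8), median 0.38 (adjusted p = 0.0147 with an estimated correlation). Rcs had 6 of 16 higher (6), median 0.32 (adjusted p = 0.000286, but adjusted p = 0.12 with an estimated correlation). Flagella had 30 of 46 lower (32), median −0.99 (adjusted p = 1.64e-15, but adjusted p = 0.118 with an estimated correlation), and TCA 7 of 30 lower (9), median −0.29 (adjusted p = 0.00433, but adjusted p = 0.198 with an estimated correlation). In all 595 genes were called at 3 h, 274 higher and 321 lower, of which 135 and 73 were 2-fold or more apart, and 233 with all 24 columns. Of 74 genes picked by the naming rule 48 kept their call with all 24 columns, and ibpA lost it.

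Earlier, at 1 h 50 min, pTN9 exceeded pHSG415 in ymfJ (3.37, SE 0.21, at least 8.8-fold), sulA (2.09, SE 0.19), dinI (1.98, SE 0.21), recN (1.67, SE 0.37), umuD (1.56, SE 0.17) and recA (1.43). It lay lower in ibpB (−2.25, SE 0.43), ibpA (−1.88, SE 0.28) and actP (−2.16). SOS had 8 of 32 higher (11), median 0.35 (adjusted p = 0.00241 with an estimated correlation), and e14 8 of 18 (10), median 1.05, or 0.47 with genes at their bound (adjusted p = 0.00597 with an estimated correlation). TCA had 1 of 30 lower (6), median −0.27 (adjusted p = 0.0142 with an estimated correlation), and oxidative 0 of 20 called (0 higher and 2 lower over the list alone), median −0.21 (adjusted p = 0.0399 with an estimated correlation). Heat shock had 2 of 24 lower (8), median −0.52 (adjusted p = 1.01e-11, but adjusted p = 0.12 with an estimated correlation). General stress (−0.23), flagella (0.25), ribosomal (0.12), purine (0.29) and toxin-antitoxin (0.20) also passed with the preset correlation only. The count was 32, 21 higher and 11 lower, and 13 with all 24 columns; it was 104 without pTN9 replicate 1, 14 without pTN9 replicate 2 and 14 without pHSG415 replicate 1. Of 17 genes picked by the naming rule 9 kept their call with all 24 columns; recN, ibpA, ibpB and actP lost it. At 1 h limma called 0 genes, with 262 at unadjusted p under 0.05 and 0 with all 24 columns. The flagella list was higher at 1 h, median 0.32 with 0 genes called (adjusted p = 2.98e-12, but adjusted p = 0.157 with an estimated correlation). TCA (0.14) and e14 (0.30) also passed with the preset correlation only.

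At 0 h the heat shock list was lower in pTN9 than in pHSG415 in 22 of 24 genes (22), median −1.61 (adjusted p = 4.23e-32; adjusted p = 0.0142 with an estimated correlation). Its genes ibpB (−4.63, SE 0.43), ibpA (−4.40, SE 0.28), clpB (−2.60, SE 0.20) and htpG (−2.31) led the fall, with tnaA (−4.16, SE 0.26) and btsT (−3.23). Higher were ymfL (3.88, at least 3.81-fold), ymfJ (3.60, at least 6.71-fold), ilvC (2.62, SE 0.23) and sulA (1.76, SE 0.19). General stress had 8 of 19 lower (11), median −0.60 (adjusted p = 0.0438 with an estimated correlation). Cpx had 5 of 15 lower and 1 higher (7 and 1), median −0.46 (adjusted p = 0.0399 with an estimated correlation). The e14 list had 10 of 18 higher (13), median 1.18, or 0.49 with genes at their bound (adjusted p = 0.0165 with an estimated correlation). SOS had 8 of 32 higher (9), median 0.21 (adjusted p = 0.00132, but adjusted p = 0.12 with an estimated correlation). Ribosomal (0.10), iron (0.39), TCA (−0.36), purine (0.32) and reductases (−0.75) also passed with the preset correlation only. The count was 381, 164 higher and 217 lower, and 98 with all 24 columns; it was 223 without pTN9 replicate 1, 182 without pHSG415 replicate 1 and 246 without pHSG415 replicate 2. Of 49 genes picked by the naming rule 20 kept their call with all 24 columns, and tnaA lost it.

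The comparisons of pTN9 with pTN11 and with pHSG415 shared 443 calls at 3 h, 205 higher and 238 lower, with 0 in opposite directions, among them sulA, umuD, recA and ymfL. Independent calls would share 22.3 and 34.9 of the 3476 genes. Both comparisons use the same pTN9 arrays, and part of the excess may come from that. The covariance of the 2 comparisons was 0.379, against 0.0248 in 100 simulations with no true difference. The simulations drew each gene independently. They hold no deviation common to many genes of a pTN9 array, so they cannot measure what that would add to the overlap. At 0 h they shared 318, 132 higher and 186 lower, with 0 opposite, where independent calls give 16.8 and 22.7, and the covariance was 0.255 against 0.0249. The shared calls at 1 h 50 min were 25, 17 higher and 8 lower, where independent calls give 0.187 and 0.0601, and the covariance was 0.109 against 0.0248.

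Did modification alone change transcripts? Between pTN11 and pHSG415 limma called 0 genes at 0 h, 0 at 1 h and 0 at 1 h 50 min, and 1 at 3 h (bla is not among the genes counted). That one was ygcU (b2773), for a putative oxidoreductase, higher in pTN11 by 1.88 (SE 0.29, adjusted p = 0.0194, at least 1.18-fold with pHSG415 at background). At unadjusted p under 0.05 there were 313, 133, 53 and 347. A share of 0.05 of the 3476 genes tested is expected by chance where none differ. The self-test did not cover this comparison, so the lack of calls does not show that the strains were equal. With all 24 columns the counts were 0, 0, 0 and 0. At 0 h the count was 17 without pTN11 replicate 2 and 1 without pHSG415 replicate 1. At 3 h it was 0 without pTN11 replicate 1, 0 without pTN11 replicate 2, 3 without pHSG415 replicate 1 and 2 without pHSG415 replicate 2. No list passed with both correlations; heat shock at 0 h had a median of −0.43 with 0 genes called (0 higher and 10 lower over the list alone; adjusted p = 1.49e-14), but adjusted p = 0.535 with an estimated correlation. Others passed with the preset correlation only. At 0 h these were ribosomal (−0.11), purine (−0.21) and reductases (0.21), and at 1 h flagella (0.15) and TCA (0.12). They were heat shock (0.21), ribosomal (−0.13) and purine (−0.19) at 1 h 50 min, and iron (−0.15) and Rcs at 3 h. Rcs was lower in pTN11 by a median of −0.29 with 0 genes called (0 higher and 5 lower over the list alone; adjusted p = 0.0339; adjusted p = 0.842 with an estimated correlation).

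The comparison of each time with 0 h asks what changed after the shift. Per the protocols the antibiotic was also removed and the culture diluted, so temperature, dilution and growth stage cannot be told apart here. In all 3 strains tnaC, the leader of the tryptophanase operon, fell at 1 h (−5.35 in pTN9, at least 30.0-fold, −6.59 in pTN11, −6.45 in pHSG415), as did lldR, a regulator of lactate use (at least 17.3-fold, 53.2-fold and 43.2-fold). The chaperone and deglycase gene hchA rose (at least 17.0-fold in pTN9, by 4.05 in pTN11 and 4.25 in pHSG415). The 46 flagellar genes all fell at 1 h and at 3 h in every strain, with medians of −2.62 and −4.26 in pTN9, −2.80 and −2.97 in pTN11 and −3.04 and −3.23 in pHSG415. TCA medians at 1 h and 3 h were −1.42 and −1.74 in pTN9, −1.70 and −1.52 in pTN11, and −1.99 and −1.74 in pHSG415. General stress rose at 1 h 50 min in 19, 18 and 19 of 19 genes (medians 1.69, 1.70, 1.61), and iron uptake fell in 20, 18 and 21 of 24 (−1.66, −1.27, −1.32). These lists passed the test with an estimated correlation too (largest adjusted p = 0.0157 among them). TCA did not at 1 h 50 min, with medians of 0.22, 0.37 and 0.26 in pTN9, pTN11 and pHSG415 (adjusted p = 0.515, 0.439 and 0.408 with an estimated correlation); under the deposited scaling they were −0.51, −0.12 and −0.29, and with all 24 columns pTN11 stood at −0.77. At 1 h and 3 h general stress was not called in pTN11 (medians −0.02 and −0.04) or in pHSG415 (0.04 and −0.11). In pTN9 it was not called at 1 h (0.46, adjusted p = 0.151) and rose at 3 h in 15 of 19 genes (1.40, adjusted p = 0.0379 with an estimated correlation). Iron was called at neither 1 h nor 3 h in any strain. Fimbriae rose in pTN9 at 1 h (9 of 12 genes higher and 1 lower) and at 1 h 50 min (9 and 0), with medians of 1.04 and 1.22, or 0.25 and 0.51 with genes at their bound (adjusted p = 0.0432 at each with an estimated correlation). In pTN9 at 3 h (median 0.91), and in pTN11 and pHSG415, they passed with the preset correlation only. Reductases fell in pTN11 at 1 h 50 min in 4 of 8 genes, median −1.30, or −1.10 with genes at their bound (adjusted p = 0.0335 with an estimated correlation). Ribosomal, purine, peptidoglycan, toxin-antitoxin, Cpx, porins and Qin passed at 1 or more times with the preset correlation only, as did flagella at 1 h 50 min in each strain and e14, lower, at 1 h in pTN9.

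The change from 0 h differed between pTN9 and pTN11 in 167 genes at 1 h, 55 at 1 h 50 min and 934 at 3 h. Compared directly, the strains differed in 721 genes at 0 h and in 661 at 3 h. Below, 3 h is meant where no other time is named. At 1 h and 1 h 50 min pTN11 had fewer arrays. In pTN9 recN was higher than at 0 h by 5.04 (SE 0.37), umuD by 4.67 (SE 0.17) and recA by 2.79 (SE 0.17). The pTN9 arrays for recN at 0 h lay far apart, as given above, so the size of its change from 0 h is less sure. By comparison recA rose by 0.96 (SE 0.17, limma adjusted p = 0.000194) in pTN11 and by 0.57 (adjusted p = 0.012) in pHSG415. SOS rose in pTN9 in 28 of 32 genes and fell in 2, median 1.16 (adjusted p = 0.00807 with an estimated correlation), and e14 in 15 of 18, median 3.27, or 3.05 with genes at their bound (adjusted p = 0.0379 with an estimated correlation). SOS did not pass in pTN11 (10 and 2 genes, adjusted p = 0.269) or in pHSG415 (13 and 6, adjusted p = 0.396); the difference in change between pTN9 and pTN11 had a median of 1.24. The tryptophanase gene tnaA fell in pTN11 (−7.88, at least 79.6-fold), in pHSG415 (−7.90, at least 49.8-fold) and less in pTN9 (−1.32, adjusted p = 0.000484), where it was lower at 0 h. Heat shock genes rose at 1 h in pTN9 (18 of 24, median 0.97) but not in pTN11 (median −0.11) or pHSG415 (17 lower, −0.67), though adjusted p = 0.328 with an estimated correlation in pTN9 and 0.469 in pHSG415. The difference in change between pTN9 and pTN11 at 1 h was not past the threshold with an estimated correlation (median 1.16, 11 of 24 genes higher, 18 over the list alone; adjusted p = 8.66e-15, but adjusted p = 0.0879 with an estimated correlation).

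The counts against 0 h were, in time order, 1404, 1580 and 1671 in pTN9, 1379, 1064 and 1743 in pTN11, and 1606, 1597 and 1602 in pHSG415. With all 24 columns they were 814, 956 and 1174, then 1090, 512 and 1068, then 985, 1000 and 966. Genes shared by the 3 strains numbered 467 higher and 340 lower at 1 h (53.4 and 17.3 if independent), 476 and 397 at 1 h 50 min (31.0 and 24.8), and 461 and 334 at 3 h (81.1 and 25.8). Under the deposited scaling the higher share in pTN9 moved from 60.7% to 49.2% at 1 h, from 52.2% to 33.5% at 1 h 50 min and from 58.6% to 48.4% at 3 h. The share at 1 h 50 min moved from 52.1% to 35.0% in pTN11 and from 51.3% to 35.1% in pHSG415, and the medians of all log2 changes shifted by −0.21, −0.16 and −0.18 in pTN9, pTN11 and pHSG415.

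**Figure D3:**
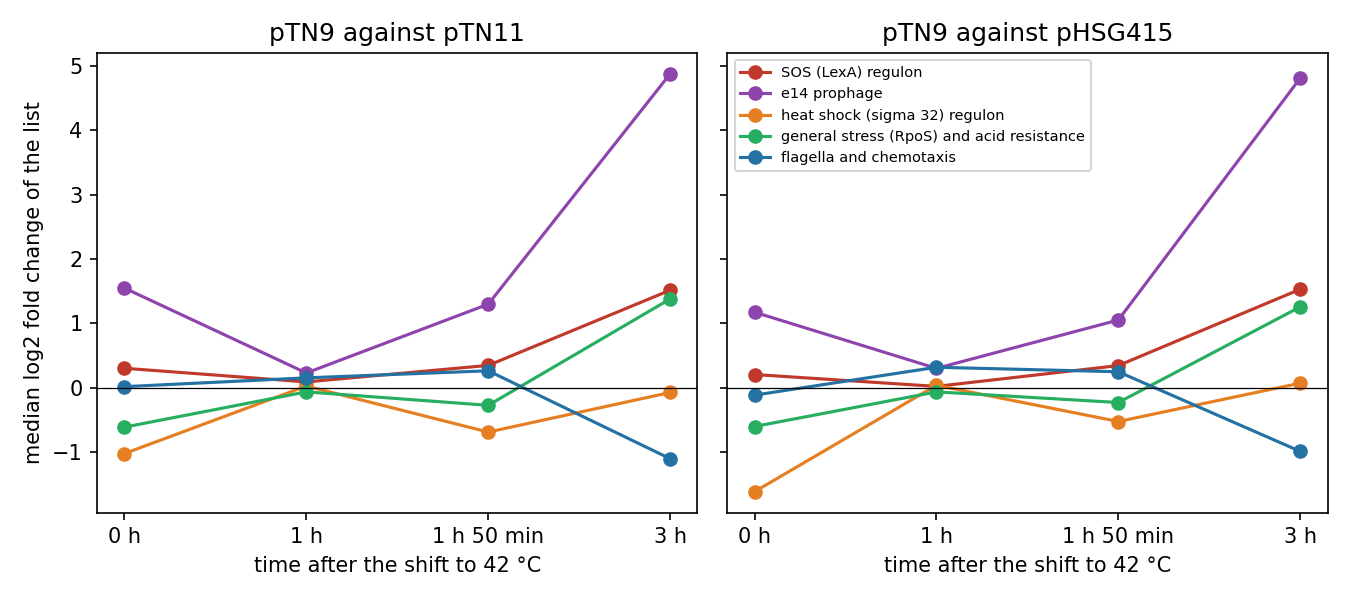
Median log2 fold change of SOS, e14, heat shock, general stress and flagella genes in pTN9 against pTN11 and against pHSG415 at the 4 times.

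The last comparison asks which changes from 0 h differed between pTN9 and pTN11. Where a group lay below background, the value with that group set to background is given beside. This holds for the genes named, the lists that passed with both correlations, and e14. A positive value means that pTN9 rose more or fell less than pTN11. At 3 h the difference was positive for tnaA (6.56, SE 0.37; 4.998 at background), stfE (5.31, SE 0.50; 3.26 at background), intE (4.41; 4.14 at background), ibpA (4.36), recN (4.28), umuD (4.21), spy (3.85), osmY (3.84), sulA (3.12, SE 0.26) and recA (1.83, SE 0.24), and negative for flgI (−2.96; −1.68 at background) and ycdZ (−2.82). The e14 list had 14 of 18 genes higher and 1 lower (15 and 1), median 3.59, or 3.43 at background (adjusted p = 0.0218 with an estimated correlation), SOS 21 of 32 higher (23), median 1.24, or 1.17 at background (adjusted p = 0.016 with an estimated correlation). General stress had 13 of 19 higher (15), median 1.53, or 1.30 at background (adjusted p = 0.0218 with an estimated correlation). Heat shock had 15 of 24 higher (17), median 0.95, but adjusted p = 0.239 with an estimated correlation. At 1 h ibpB (4.20, SE 0.69), dsdA (3.96; 3.85 at background) and ibpA (3.64, SE 0.44) had a positive difference and ymfL (−3.82, SE 0.41; −1.22 at background) and sulA (−1.17, SE 0.30) a negative one. At 1 h 50 min tnaA (4.10, SE 0.42), glpC (3.85) and btsT (3.57; 3.01 at background) had a positive difference and ilvC (−2.38, SE 0.36) a negative one. The reductases had a positive difference at 1 h, median 0.96, or 1.18 at background, with 5 of 8 genes (6; adjusted p = 0.0474 with an estimated correlation). It was 1.03 at 1 h 50 min, or 1.09 at background, with 2 (5; adjusted p = 0.0218 with an estimated correlation). These follow from the lower level of pTN9 at 0 h, since the strains stood 0.10 and 0.11 apart at those times. Against 0 h the list was not called in pTN9 at either time (0.31 and −0.88; adjusted p = 0.328 and 0.123), with 5 of 8 genes lower at 1 h 50 min, when pTN11 fell by −1.30. Oxidative at 3 h had 7 of 20 higher (8), median 0.44, or 0.59 at background (camera adjusted p = 0.0474 with an estimated correlation). The lists below passed with the preset correlation only. At 1 h these were SOS (−0.24), Cpx (0.37), ribosomal (−0.25), general stress (0.48), iron (−0.34), TCA (0.24), purine (−0.40) and e14 (−0.996, or −0.15 at background). They were heat shock (0.54), sigma E (0.24), Cpx (0.35), flagella (0.25) and iron (−0.29) at 1 h 50 min. At 3 h they were Rcs (0.55), flagella (−1.21), ribosomal (−0.32), purine (−0.79) and reductases (0.90). The difference at 1 h 50 min was 0.088 and not called with all 24 columns (adjusted p = 0.557).

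The counts of such genes were 167 at 1 h (110 higher, 57 lower), 55 at 1 h 50 min (41 and 14) and 934 at 3 h (423 and 511), and 26, 33 and 273 with all 24 columns. At 1 h the count was 102 without pTN9 replicate 1 at 0 h and 95 without pTN9 replicate 1 at 1 h, and at 1 h 50 min 33 without pTN9 replicate 1 at 0 h. Under the deposited scaling the higher share moved from 65.9% to 43.7%, from 74.5% to 62.2% and from 45.3% to 28.8%, and the median of all log2 differences shifted by −0.13 at 1 h and −0.19 at 3 h. Of the genes named, sulA at 1 h, tnaA and btsT at 1 h 50 min and tnaA at 3 h lost their call with all 24 columns. So did the followed genes groL and clpB at 1 h and at 3 h.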

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

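The tests on the identical columns were chosen after the result was seen; the bounds of the other tests were written before, but a margin of 2 standard errors and the conditions for a void test were added after the values were seen.

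The change from 0 h differed between pTN9 and pTN11 by a test of the interaction itself. At 1 h 167 genes differed, with sulA at −1.17, dnaK at 1.89, groL at 1.55, ibpA at 3.64, clpB at 1.72 and spy at 2.38, and the reductases at a median of 0.96. With all 24 columns sulA, groL and clpB lost this call. At 1 h 50 min 55 genes differed, with spy at 2.12 and the reductases at 1.03, but at 0.088 and not called with all 24 columns (adjusted p = 0.557). At 3 h 934 differed, with recA at 1.83, lexA at 1.69, sulA at 3.12, umuD at 4.21, dinI at 2.00, recN at 4.28, dnaK at 2.11, groL at 1.13, ibpA at 4.36, clpB at 1.76, degP at 1.47, spy at 3.85 and ompF at −0.98, of which groL and clpB lost the call with all 24 columns. The list medians at 3 h were 1.24 for SOS, 1.53 for general stress, 0.44 for oxidative and 3.59 for e14, or 3.43 for e14 with groups below background set to background. Each includes any difference already present at 0 h, when the heat shock genes, spy and the reductases (−1.07) were lower in pTN9 and sulA was higher (1.78). At 1 h neither the reductases (0.10) nor sulA (0.61) differed by a call.

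Intergenic probe sets, which enter no comparison above, also differed from the controls. Of 2355 tested, limma called 81 between pTN9 and pTN11 at 0 h (32 higher, 49 lower), 0 at 1 h (107 at unadjusted p under 0.05), 2 at 1 h 50 min and 179 at 3 h (73 and 106). Against pHSG415 the counts were 50 (15 and 35), 0 (259 at unadjusted p under 0.05), 3 and 115 (55 and 60). The 26 phage and plasmid probe sets among them gave 0 calls. Among the highest at 3 h were the probe sets named for positions 1201284 to 1201481 (at least 117-fold) and 1200256 to 1200291 (at least 36.0-fold), on the reverse strand, in the numbering of the array, whose genome build is not given in the sources used here.

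The first pattern weighed is the column of values found under 2 labels, pTN11 at 1 h and at 1 h 50 min. A 1 h 50 min culture is argued against: the highest correlation with the 5 other 1 h 50 min arrays was 0.879, and the lowest among those arrays 0.977. A 1 h culture like the others is argued against too: the correlation with the 5 other 1 h arrays ran from 0.966 to 0.976, and the lowest among them was 0.984. The column correlated at up to 0.974 with 3 h arrays, so a culture from yet another source stays open, as does a 1 h culture of another experiment. No biological explanation was tested.

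The second pattern is the lower heat shock genes of pTN9 at 0 h. The scaling is argued against: under the deposited scaling the list median was −0.867 against pTN11 (adjusted p = 1.39e-14) and −1.66 against pHSG415. A difference in growth stage between the 0 h cultures is a candidate explanation, not shown for the list itself. Over 3452 genes outside the list, the 0 h difference from pHSG415 was set beside pTN11 at 1 h 50 min minus 1 h. These ran opposite ways (Spearman rho −0.375, and −0.471 with the controls exchanged). Per the series text, however, growth at 30 °C was alike by OD660. Since rho leaves out the list, it cannot show that growth stage accounts for the heat shock genes. Against 0 h the list median was −0.11 at 1 h and 0.07 at 1 h 50 min in pTN11. In pHSG415 it was −0.67 and −0.56. Heating of the control cultures before harvest stays open. Here the 0 h difference was taken the other way round, as pHSG415 minus pTN9. Its rho with the change of pTN11 from 0 h to 1 h was −0.346 (−0.360 with the controls exchanged). Heating was predicted to give a positive rho. However, the change of pTN11 has no raised heat shock list (median −0.11, and −0.67 in pHSG415), which leaves the test void. The plasmid each strain carries is a biological difference of the design and stays open, untested.

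The last pattern is the 661 genes that differ from pTN11 at 3 h and the 595 that differ from pHSG415. The scaling is argued against: 88.7% of the calls against pTN11 and 90.9% of those against pHSG415 were kept in the same direction under the deposited scaling. Gene dosage along the replication arms cannot be told apart: rho with gene order distance from oriC was −0.0915 against pTN11 and −0.0858 against pHSG415, too close to the bound of 0.1 to exclude a weak trend. A later growth stage of the pTN9 culture stays open likewise: over 3426 genes outside SOS and e14, rho with the change of pHSG415 from 1 h to 1 h 50 min was 0.0981 and that with the controls exchanged 0.127 (SE 0.0171). Restriction by PaeR7I, the difference between pTN9 and pTN11 that the design names, stays open, and no test here separates it from the others.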

How the results depend on the processing

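The settings that keep the identical pTN11 column were chosen after the data were seen; the others were planned. Of 468 recomputed counts 375 stayed within 1.5 times the value reported. Of 8154 recomputed gene results 7096 kept their direction and their side of the threshold, and so did 2528 of 2817 list results. SOS (medians 1.17 to 1.56), e14 (3.08 to 5.90), general stress (0.77 to 1.48), Rcs (0.41 to 1.31) and oxidative (0.29 to 0.47) did so at 3 h against pTN11 in all 16 alternatives, with highest adjusted p of 0.00072, 0.00235, 0.0159, 0.0314 and 0.0291. So did e14 at 0 h (0.59 to 1.98) and, against pHSG415, heat shock at 0 h (−1.74 to −1.45). A list whose direction turned below while its median kept its sign is one where the camera direction turned, mostly far from the threshold. Where no cause is given, the cause was not tested.

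With all 24 columns, the fit as first designed, the counts fell from those reported. In that fit 18 counts left the range given at the start of this section. So did 18 with the identical column kept at 1 h 50 min only, but 1 with it kept at 1 h only. The fall thus went mostly with the column's place at 1 h 50 min. Its correlation with the other arrays of that time was at most 0.879, and the lowest among those arrays was 0.977. The fit uses the same estimate of each gene's spread for every comparison. A column unlike the other array of its group adds to that estimate, so it can lower counts at other times too. How much of the fall came this way was not measured. For pTN9 against pTN11 the counts with all 24 columns were 162 at 0 h, 0 at 1 h, 28 at 1 h 50 min and 218 at 3 h. For pTN9 against pHSG415 they were 98 at 0 h, 13 at 1 h 50 min and 233 at 3 h, and for pTN11 against pHSG415 0 at 3 h. Against 0 h they were 814 and 956 in pTN9 at 1 h and 1 h 50 min, 512 and 1068 in pTN11 at 1 h 50 min and 3 h, and 985, 1000 and 966 in pHSG415. For the difference in change they were 26, 33 and 273. At 1 h 50 min against pTN11, TCA turned to a median of 0.73 (from −0.35), as did yjcH to 0.44, lhgD to 0.12, gabD to 0.50, sucD to 0.59, gltA to 1.10, sucC to 0.60 and sucB to 1.03, oxidative lost its call (0.0033), general stress turned to 0.71 (from −0.27) and Rcs to −0.098, and ribosomal (0.036), purine (0.15) and fimbriae (0.36) lost their call. So did phage shock at 1 h (−0.14), and TCA at 0 h against pTN11 (−0.38) and against pHSG415 (−0.37, and 0.142 at 1 h). Between pTN11 and pHSG415 calls were lost by reductases at 0 h (0.21), flagella (0.072) and TCA (0.072) at 1 h, heat shock at 1 h 50 min (0.13) and iron at 3 h (−0.15), while ribosomal (0.10) and purine (0.034) turned at 1 h 50 min. In the difference in change they were lost by SOS (−0.24), iron (−0.245) and TCA (0.40) at 1 h and sigma E at 1 h 50 min (0.035), where e14 turned (0.015). In pTN11 at 1 h 50 min against 0 h, TCA turned to −0.77 (from 0.37), SOS to 0.068, heat shock to −0.12 and sulA to −0.075. In the difference in change at 1 h 50 min malE turned to 0.42 and the reductases lost their call (0.088). At 3 h against pTN11 fimbriae (−0.58) and Qin (−0.40) gained a call and reductases turned (−0.31). Heat shock against pTN11 at 1 h turned (−0.067), as did SOS in pTN9 at 1 h (0.16) and iron in pTN11 at 1 h (0.088), and TCA in pHSG415 at 1 h 50 min lost its call (0.26).

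With the column kept at 1 h 50 min only, the counts were near those with all 24. For pTN9 against pTN11 they were 161 at 0 h, 19 at 1 h 50 min and 213 at 3 h, for pTN9 against pHSG415 104, 13 and 221, and for pTN11 against pHSG415 0 at 3 h. Against 0 h they were 818 and 965 in pTN9 at 1 h and 1 h 50 min, 671, 531 and 1068 in pTN11, and 988, 973 and 973 in pHSG415, and for the difference in change 22, 35 and 269. At 1 h 50 min against pTN11, TCA turned to 0.73, yjcH to 0.45, lhgD to 0.13, gabD to 0.51, sucD to 0.59, gltA to 1.10, sucC to 0.60 and sucB to 1.03, oxidative lost its call (0.0036), general stress turned to 0.72 and Rcs to −0.099, and ribosomal (0.036), purine (0.16) and fimbriae (0.37) lost their call. So did flagella at 1 h (0.15), and TCA at 0 h against pTN11 (−0.37) and against pHSG415 (−0.362, and 0.141 at 1 h). Between pTN11 and pHSG415 calls were lost by reductases at 0 h (0.21), TCA at 1 h (0.12), heat shock at 1 h 50 min (0.13) and iron at 3 h (−0.15), while ribosomal (0.10) and purine (0.035) turned at 1 h 50 min. In the difference in change they were lost by general stress (0.47), iron (−0.29) and TCA (0.24) at 1 h and sigma E at 1 h 50 min (0.036), where e14 turned (0.015). In pTN11 at 1 h 50 min SOS turned to 0.068, heat shock to −0.12, TCA to −0.77 and sulA to −0.076. At 3 h against pTN11 TCA lost its call (−0.39), Qin gained one (−0.41) and reductases turned (−0.31). SOS in pTN9 at 1 h (0.16), iron in pTN11 at 1 h (0.11) and malE in the difference at 1 h 50 min (0.42) turned. TCA in pHSG415 at 1 h 50 min (0.26) and the reductases in the difference at 1 h 50 min (0.086) lost their call. With the column kept at 1 h only, against pTN11 the count at 1 h was 0, heat shock at 1 h turned (−0.067), phage shock at 1 h lost its call (−0.14) and Rac at 3 h turned (−0.0091), and iron in pHSG415 at 1 h turned (0.16). Flagella (0.072) and TCA (0.073) between pTN11 and pHSG415 at 1 h and iron in the difference at 1 h (−0.245) lost their call.

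Fitting only the arrays of one time leaves fewer residual degrees of freedom. It gave 435, 0, 14 and 434 genes for pTN9 against pTN11 in time order, 202 at 0 h, 3 at 1 h and 13 at 1 h 50 min for pTN9 against pHSG415, and 0 for pTN11 against pHSG415 at 3 h. At 1 h 0 lists passed against pTN11 (4 reported), e14 (0.22), phage shock (−0.12), flagella (0.15) and anaerobic (−0.032) there lost their call, and at 3 h Rac turned (−0.050) and Qin gained a call (−0.37).

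The deposited scaling gave 0 genes at 1 h and 28 at 1 h 50 min against pTN11, and 2 at 1 h against pHSG415. Calls were lost by TCA at 0 h against pTN11 (−0.042) and against pHSG415 (−0.18, and 0.13 at 1 h) and by anaerobic at 1 h against pTN11 (−0.095). They were lost by reductases between pTN11 and pHSG415 at 0 h (0.12), and in the difference in change by SOS (−0.37), iron (−0.48) and TCA (−0.10) at 1 h and sigma E (0.10) and flagella (−0.0037) at 1 h 50 min. Against pTN11 heat shock at 1 h turned (−0.0088), at 3 h porins lost their call (−0.25), ribosomal turned and gained a call (0.18), and Rac turned (−0.034). Against 0 h SOS in pTN9 at 1 h turned (0.020), and in pTN9 at 1 h 50 min heat shock lost its call (−0.0087) while TCA (−0.51) and ompC (−0.58) turned. Iron in pTN11 at 1 h (0.031), heat shock in pTN11 at 1 h 50 min (−0.30) and TCA in pHSG415 at 1 h 50 min (−0.29) turned, and TCA in pTN11 at 1 h 50 min lost its call (−0.12). This scaling shifts all genes at 1 h 50 min, by the medians given with the changes from 0 h.

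SOS in the difference in change at 1 h 50 min gained a call with the pseudocount at the 25th percentile (0.19), a pseudocount of 1 (0.13), no intensity trend (0.21) and the replicate block (0.24). The pseudocount at the 25th percentile gave 2 genes at 1 h against pTN11, Rac turned (−0.041) and Qin gained a call (−0.37) at 3 h, and iron in pTN11 at 1 h turned (0.0038). A pseudocount of 1 gave 64 genes for pTN9 against pHSG415 at 1 h 50 min and 0 for pTN11 against pHSG415 at 3 h. With it Rac turned (−0.025), Qin gained a call (−0.25), and SOS in pTN9 at 1 h (0.12), iron in pTN11 at 1 h (0.0029) and e14 in the difference at 1 h 50 min (0.053) turned. With no filter there was 1 gene against pTN11 at 1 h and 1 for pTN11 against pHSG415 at 0 h. Porins lost their call (−0.18), as did anaerobic at 1 h (−0.018) and fimbriae at 1 h 50 min (0.13), Rac turned (−0.021), general stress in pHSG415 at 1 h turned (0.046), and fimbriae in pTN9 at 1 h 50 min lost its call (0.30). The filter of 40% tests fewer genes and gave 1 gene at 1 h and 0 at 3 h for pTN11 against pHSG415, and 2 lists at 1 h for pTN9 against pTN11. With it fimbriae (−0.47), reductases (−0.33) and Rac (0.18) turned at 3 h, as did Rcs at 1 h 50 min against pTN11 (−0.21), SOS in pTN9 at 1 h (0.19), iron in pTN11 at 3 h (−0.035) and iron in pHSG415 at 1 h (0.49). Calls were lost by phage shock (−0.11) and anaerobic (−0.014) at 1 h and fimbriae (0.50) at 1 h 50 min against pTN11, and by toxin-antitoxin at 1 h 50 min against pHSG415 (0.20). They were lost by reductases at 0 h (0.13) and Rcs (0.20) and iron (−0.15) at 3 h between pTN11 and pHSG415, by fimbriae in pTN9 at 1 h 50 min (1.40) and by iron in the difference at 1 h (−0.24). With no intensity trend there were 0 genes against pTN11 and 2 for pTN9 against pHSG415 at 1 h, and 2 for pTN11 against pHSG415 at 3 h. Qin gained a call (−0.41), and SOS in pTN9 at 1 h (0.16) and iron in pTN11 at 1 h (0.0044) turned.

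The replicate block gave 2 genes and 2 lists for pTN9 against pTN11 at 1 h, and the other counts stayed within 1.5 times the value reported. Rcs at 1 h 50 min against pTN11 turned (0.029), and phage shock (−0.098) and anaerobic (−0.038) at 1 h lost their call, as did purine between pTN11 and pHSG415 at 1 h 50 min (−0.16). Across the 10 groups with 2 arrays, 45 correlations of replicate differences ran from −0.241 to 0.441, median 0.0097, with 13 above 0.1. Replicate numbers thus showed no pairing common to all groups, but pairing among some of them is not excluded.

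The estimated inter-gene correlation left 2, 0, 4 and 5 lists for pTN9 against pTN11 in time order (10, 4, 10 and 8 reported with the preset one) and 4, 0, 4 and 4 for pTN9 against pHSG415 (10, 3, 10 and 7). The medians do not change with this setting. Calls were lost against pTN11 for SOS (0.30), heat shock (−1.02), ribosomal (0.22), general stress (−0.61), purine (0.48), Cpx (−0.42), iron (0.35) and TCA (−0.37) at 0 h, e14 (0.23), phage shock (−0.12), flagella (0.16) and anaerobic (−0.061) at 1 h, heat shock (−0.69), flagella (0.26), general stress (−0.27), ribosomal (0.28), purine (0.39) and fimbriae (0.37) at 1 h 50 min, and porins (−0.23), flagella (−1.10) and TCA (−0.39) at 3 h. Against pHSG415 they were lost for SOS (0.21), ribosomal (0.10), iron (0.39), TCA (−0.36), purine (0.32) and reductases (−0.75) at 0 h, and for e14 (0.30), flagella (0.32) and TCA (0.14) at 1 h. They were lost there too for heat shock (−0.52), flagella (0.25), general stress (−0.23), ribosomal (0.12), purine (0.29) and toxin-antitoxin (0.20) at 1 h 50 min, and for Rcs (0.32), flagella (−0.99) and TCA (−0.29) at 3 h. Between pTN11 and pHSG415 they were lost for heat shock (−0.43), ribosomal (−0.11), purine (−0.21) and reductases (0.21) at 0 h, flagella (0.15) and TCA (0.12) at 1 h, heat shock (0.21), ribosomal (−0.13) and purine (−0.19) at 1 h 50 min, and Rcs (−0.29) and iron (−0.15) at 3 h. In the difference in change they were lost at 1 h for heat shock (1.16), SOS (−0.24), Cpx (0.37), ribosomal (−0.25), general stress (0.48), iron (−0.34), TCA (0.24), purine (−0.40) and e14 (−0.996). The same held at 1 h 50 min for heat shock (0.54), sigma E (0.24), Cpx (0.35), flagella (0.25) and iron (−0.29), and at 3 h for heat shock (0.95), Rcs (0.55), flagella (−1.21), ribosomal (−0.32), purine (−0.79) and reductases (0.90). Against 0 h they were lost for heat shock in pTN9 (0.97, 0.42 and 0.83 in time order) and in pHSG415 (−0.67, −0.56 and −0.74). Flagella lost the call at 1 h 50 min (−0.99, −1.18 and −1.26 in pTN9, pTN11 and pHSG415), as did TCA in pTN11 (0.37) and pHSG415 (0.26).

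Leaving out each array in turn, a lone array left in a group is assumed to vary like the other groups. Counts then ran, for pTN9 against pTN11, from 396 to 635 at 0 h, 0 to 3 at 1 h, 13 to 86 at 1 h 50 min and 320 to 723 at 3 h. For pTN9 against pHSG415 they ran from 182 to 359 at 0 h and 14 to 104 at 1 h 50 min, and for pTN11 against pHSG415 from 0 to 17 at 0 h and 0 to 3 at 3 h. For the difference in change they ran from 95 to 196 at 1 h and 33 to 71 at 1 h 50 min. Lists past the threshold against pTN11 at 1 h numbered 1 to 3. List medians against pTN11 at 1 h ran from 0.0063 to 0.11 for heat shock and 0.26 to 0.29 for e14, whose call was lost without pTN9 replicate 2 at 1 h. Rcs ran from −0.013 to 0.18 at 0 h and 0.028 to 0.13 at 1 h 50 min. Flagella at 1 h 50 min ran from 0.18 to 0.35 against pTN11 and 0.15 to 0.34 against pHSG415, with the call lost without pTN9 replicate 1, as was that of fimbriae there against pTN11 (0.361 to 0.362). Against pTN11, TCA at 0 h ran from −0.50 to −0.24, with the call lost without pTN11 replicate 2. At 1 h flagella ran from −0.043 to 0.38, turning without pTN9 replicate 1, phage shock from −0.12 to −0.086, with the call lost without replicate 2, and anaerobic from −0.090 to −0.034, with the call lost without either. Against pHSG415, ribosomal at 0 h ran from 0.084 to 0.15, with the call lost without pHSG415 replicate 1, and TCA from −0.40 to −0.34, with the call lost without pTN9 replicate 1. TCA at 1 h ran from 0.023 to 0.16, with the call lost in 3 of 4 omissions. Purine at 1 h 50 min ran from 0.014 to 0.52, with the call lost without pTN9 replicate 2, and toxin-antitoxin from 0.18 to 0.25, with the call lost in 3 of 4. At 3 h against pTN11 they ran from −0.13 to −0.0011 for heat shock, −0.064 to 0.077 for Cpx, −0.066 to 0.12 for peptidoglycan and −0.075 to 0.016 for Rac. There porins ran from −0.39 to −0.13, with the call lost without pTN9 replicate 2, and TCA from −0.40 to −0.24, with the call lost without pTN9 replicate 1. Without pTN9 replicate 1 a call was gained by ribosomal (range −0.14 to −0.047), iron (0.15 to 0.27) and Qin (−0.51 to −0.33). Against 0 h SOS in pTN9 at 1 h ran from 0.012 to 0.26, heat shock in pTN11 from −0.35 to 0.071 at 1 h, −0.10 to 0.21 at 1 h 50 min and −0.25 to 0.085 at 3 h, with a call at 1 h and 3 h without pTN11 replicate 1 at 0 h. TCA at 1 h 50 min ran from 0.16 to 0.44 in pTN11 and 0.23 to 0.29 in pHSG415, with the call lost without replicate 1 at 0 h of each. Iron in pHSG415 at 1 h ran from 0.042 to 0.30. Between pTN11 and pHSG415 the lists that follow lost their call in 1 or more omissions. Ranges at 0 h were −0.16 to −0.034 for ribosomal, −0.38 to −0.13 for purine and 0.14 to 0.38 for reductases, and TCA at 1 h ran from −0.0061 to 0.16. At 1 h 50 min heat shock ran from 0.072 to 0.36 and purine from −0.19 to −0.11, and at 3 h Rcs from −0.42 to −0.18 and iron from −0.23 to −0.13. In the difference in change SOS (−0.32 to −0.11), iron (−0.43 to −0.24) and TCA (0.22 to 0.41) at 1 h and sigma E (0.20 to 0.33), flagella (0.16 to 0.33) and iron (−0.35 to −0.20) at 1 h 50 min lost their call in 1 or more omissions. SOS at 1 h 50 min ran from 0.11 to 0.29, with a call without pTN9 replicate 1 or pTN11 replicate 2 at 0 h, and e14 from −0.19 to 0.18.

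Between 2841 and 3626 genes lay above background on an array. Most e14 genes lay below it in the controls, so their folds are lower bounds.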
